A study of Mus musculus with 6 samples.

How the data were processed

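Nuclei from the brains of CD-1 mice, an outbred stock, were profiled by droplet single-nucleus RNA sequencing in 6 libraries, 3 from untreated animals and 3 from animals given an anti-CD24 antibody coupled to magnetic beads. Per the labels' titles and the series' design text, replicate 1 of each group was a pilot from 1 animal with 4000 nuclei loaded. Replicates 2 and 3 of each group were pools of 3 animals with 25000 nuclei loaded. The treatment protocol field names the beads for every sample, untreated ones included, so the groups were taken from the treatment characteristic. The labels do not say whether untreated animals received uncoupled beads or an injection. The labels give neither the sex of the animals nor the dates of dissection or sequencing.

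Per the series' design text, the authors aligned the reads with Cell Ranger 7.1.0 to the pre-built mouse reference mm10 and sequenced to about 20000 reads per nucleus. The deposited matrices hold counts, whole numbers of unique molecular identifiers (UMI) per gene and barcode. Their lowest total per barcode was 500. The design text also describes an aggregation that equalised mapped reads per cell between samples, and it does not say whether the deposited counts come before or after it. The text states 44676 captured nuclei, and the deposited files hold 42119 barcodes. The files used carry no cell type labels, so types were assigned here from the counts. Gene symbols and IDs came from the files, and positions on GRCm38 came from GENCODE M21, where 32158 of 32287 feature IDs matched and 129 did not.

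Barcodes with at least 300 detected genes and at most 10% mitochondrial UMI were kept (41077). Of the pilot barcodes, 11.9% in control replicate 1 and 11.3% in beads replicate 1 lay over the mitochondrial limit, against 1.0% to 2.3% in the pools. Doublet scores came from the Scrublet method in scanpy 1.11.5. Its own limit called 26 barcodes in all, too few to have worked, so in each library the highest scores were called up to the expected share, 0.8% per 1000 barcodes. This removed 2936 nuclei and left 38141. Counts were scaled to 10000 per nucleus and log transformed. The 2000 most variable genes, without mitochondrial and sex-linked genes, gave 30 principal components, 15 exact nearest neighbours and Leiden clusters (leidenalg 0.10.2) at resolution 1.0. Nuclei of lineage clusters (stem cell, astrocyte, transit amplifying, neuroblast, ependymal) were clustered again among themselves.

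Clusters were named from marker genes fixed before the data were examined. A name needed a mean log2 enrichment of the markers of at least 1.0, a margin of 0.5 over the next type and at least 3 detected markers. Its 10 leading genes also had to hold no more markers of another type than of its own. The limits were 0.5 for lineage sub-clusters and 0.1 for striatal projection neurons, the most abundant type. Neither needed a margin over the next type, so no margin set neural stem cell-like apart from astrocyte-like sub-clusters. These limits, unlike the markers, were adjusted over several looks at the cluster tables. The sub-cluster limit was first 0.8 and was lowered after a test run because resolution 2 left no stem cell class. In the clustering used here, every named sub-cluster scored 0.97 or more; the alternative clusterings were not rechecked at 0.8. Of 32 clusters, those named hold 26239 nuclei of 14 types.

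An earlier clustering in single precision with approximate neighbours gave class memberships that shifted with the processor's instruction set, and group results had been seen under it. It was replaced by double precision with exact neighbours, which gave identical clusters under the processor settings tried and was adopted before its own group results were seen. Some calls differed between these versions, for example Cxcl2 in microglia-like nuclei, which in an earlier version fell below the expression filter. The other clustering seed, an alternative added after seeing the data, gives the remaining dependence: 1286 of 1464 astrocyte-like nuclei and 1280 of 1349 neural stem cell-like nuclei kept their name.

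For each of 10 types and for the neurogenic lineage (neural stem cell-, transit amplifying- and neuroblast-like nuclei together), counts were summed per library, since libraries and not nuclei are replicates. Libraries with under 10 nuclei of a type were left out, which left only the pools for ependymal-like and endothelial-like nuclei. edgeR 4.0.16 (R 4.3.3) tested beads against control with filterByExpr, TMM normalization and the quasi-likelihood test, with Benjamini-Hochberg adjustment and a threshold of 0.05 in each type. Levels printed for tested genes are CPM values (library-scaled counts) with TMM factors. Levels of Trpm3, Pkd1 and Pkd2 over all libraries, of Cwc22, of Npas4 over all nuclei, and of Ttr and Uty are CPM values without TMM factors. Gene lists with at least 5 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over all 277 combinations of list and type. Estimated correlations and fry were run beside it. Numbers of nuclei per type were tested with edgeR. Shares of the lineage were compared by two-sided exact permutation tests, which with 3 against 3 cannot give a p below 0.1. Intervals on shares of nuclei are exact binomial at 95% and cover counting error only.

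The genes named were fixed by rule before the data were examined. They are the genes past the threshold with at least 20 UMI per library and no overlap between groups. Where fewer than 5 passed in a type, they are the 5 with the smallest p, given as values. Added to these are the channel genes Pkd1, Pkd2, Trpm3, Piezo1 and Piezo2, a set of lineage and ependymal genes, and 4 members of each list that passed. Not every gene that the rule takes is printed. Any other gene named was chosen after its values were seen.

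Libraries with the same replicate number deviated together from their group means, with correlations across genes of 0.11 to 0.64 in the 8 types with 6 libraries. Pools of different number correlated at 0.10 to 0.50 and pilots with pools at -0.59 to -0.12, so most of the shared part lies between pilots and pools. The labels name no shared litter or day, and the check does not show that pools of the same number belong together. Over all nuclei, beads replicate 2 correlated at 0.35 with control replicate 2 and 0.40 with control replicate 3. Beads replicate 3 correlated at 0.29 with control replicate 2 and 0.20 with control replicate 3, and single types went either way. The replicate block and the sign flips within pairs therefore rest on an assumed pairing.

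The edgeR step was tested on counts simulated from each type's means and library sizes, with 200 genes changed. Each gene had the same mean in all libraries before the change, and a spread set by its level alone. The simulated counts thus hold no difference between pilots and pools, and recovery in the real counts may be lower than the shares given here. In neural stem cell-like nuclei 32% of 2-fold and 79% of 4-fold changes were recovered over 5066 genes, and in endothelial-like nuclei 24% and 79% over 4298 genes. In striatal projection neuron-like nuclei the shares were 38% and 92% over 14479 genes. DESeq2 recovered 6% and 62%, 7% and 57%, and 37% and 90% of them, respectively, so its counts of 0 exclude less than those of edgeR.

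Alternatives planned before the data were examined were DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, the replicate number as a block, a term for pilot against pool and the pooled libraries alone. Others were doublets kept, nuclei with at least 1000 UMI, Leiden resolution 2, other denominators and lineage definitions, and each library left out in turn. A mitochondrial limit of 5% and the other clustering seed were added after seeing the data. All 6 libraries were used.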

Results

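A total of 6 libraries of brain nuclei were compared, 3 from untreated mice and 3 from mice given anti-CD24 beads. With untreated mice as the control, the antibody cannot be separated from the beads or their delivery. CD24 is a surface protein carried by ependymal cells, whose cilia move the cerebrospinal fluid, and by neuroblasts. The libraries held 1814, 9305 and 10077 barcodes for control replicates 1, 2 and 3, and 2080, 9169 and 9674 for beads replicates 1, 2 and 3. Their total counts were 3668506, 18538111 and 19667519 UMI for the controls and 4171124, 20988588 and 19220072 UMI for the beads. Median counts per analysed nucleus were 1886.5, 1202.5 and 1312 UMI in the controls and 1949.5, 1539 and 1383 UMI in the bead libraries.

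Striatal projection neuron-like nuclei made up most of the named nuclei, with 14272 of 26239. Oligodendrocyte-like nuclei followed with 3075, astrocyte-like with 1464, neural stem cell-like with 1349 and microglia-like with 1022. The smaller classes included 698 neuroblast-like, 624 endothelial-like, 508 ependymal-like and 501 transit amplifying-like nuclei. The neural stem cell-like class was led by Pappa, Mir155hg, Tnfaip2, Ptx3, Thbs4, Chil1 and Gbp2b, so immune genes stood beside the stem cell marker Thbs4. The largest projection neuron cluster was led by the immediate early genes Npas4, Fosb, Egr3, Nr4a1 and Arc. Most projection neuron-like and oligodendrocyte-like nuclei of the pilots formed clusters of their own, apart from those of the pools.

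The remaining 11902 analysed nuclei stayed unnamed. Their biggest cluster had a median of 698 UMI and was led by genes of respiration and the ribosome, such as Cox6a1, Chchd10 and Rpl17. It held 0.64%, 27.69% and 29.21% of the nuclei of control replicates 1 to 3 and 0.94%, 11.22% and 13.45% of those of beads replicates 1 to 3. A naming limit set after seeing the data kept this cluster out, and the shares of types below leave it out of their denominator.

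The study's title asks whether ciliary beating of ependymal cells holds adult neural stem cells quiescent. Beads on ependymal cells bear on this through the balance of stem cells, dividing transit amplifying cells and neuroblasts. Shares of the lineage count named nuclei only, and lineage sub-clusters left unnamed are outside them. These were uneven between libraries. The sub-cluster led by S100a6, Vim and Lcn2 held 0, 58 and 89 nuclei of control replicates 1 to 3. It held 3, 73 and 192 nuclei of beads replicates 1 to 3. Another held 8, 122 and 64, and 2, 118 and 147 nuclei, and a further 1, 64 and 44, and 3, 72 and 38. Neural stem cell-like nuclei made up 57.8% ± 13.2 (SD, n = 3) of the lineage in controls and 49.9% ± 8.93 (SD, n = 3) with beads. The cycling, transit amplifying-like share was 18.3% ± 4.78 (SD, n = 3) in controls and 20.2% ± 2.81 (SD, n = 3) with beads. Both differences, -7.86 percentage points for the stem cell share of the neurogenic lineage and 1.91 for the cycling share of the neurogenic lineage, were smaller than the spread between control replicates. The exact two-sided permutation p was 0.4 for the stem cell share and 0.6 for the cycling share, and the smallest possible p was 0.1.

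The pilots and the pools went opposite ways. Stem cell-like nuclei were 71.0% of the lineage in control replicate 1 and 39.6% in beads replicate 1. In control replicates 2 and 3 they were 44.6% and 57.7%, and in beads replicates 2 and 3 they were 54.5% and 55.6%. Over the pools alone the difference was 3.89 percentage points for the stem cell share of the neurogenic lineage (exact permutation p = 1) and -1.95 for the cycling share of the neurogenic lineage (exact permutation p = 0.667), in a design whose smallest p is 0.333. The pilots are 1 library against 1, too few for a test, and control replicate 1 held 100 lineage nuclei. Without it the cycling difference was -0.726 percentage points and the stem cell difference -1.25. With the replicate block, by exact sign flips within pairs, the differences stayed at -7.86 and 1.91 with p = 0.75 for each, where the smallest p is 0.25.

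**Figure D1:**
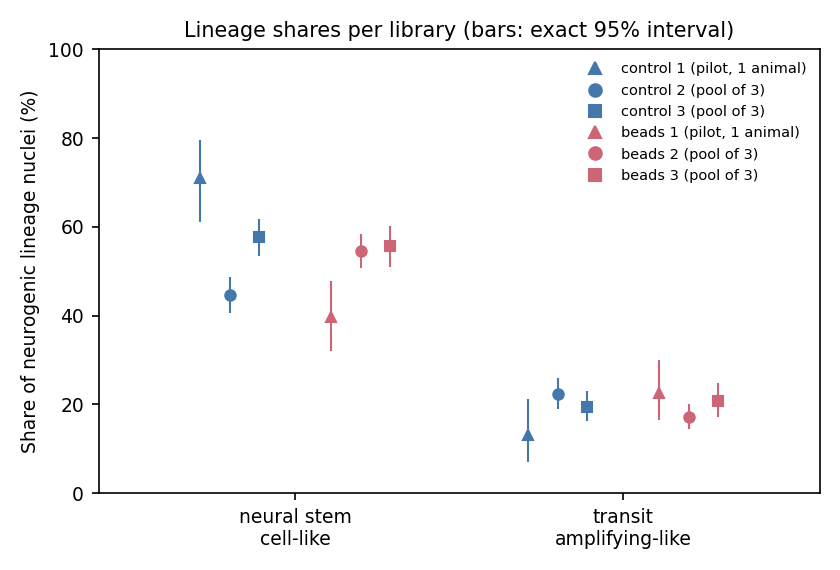
Share of neurogenic lineage nuclei (y axis, percent) that were neural stem cell-like or transit amplifying-like in each library, with exact 95% binomial intervals that cover counting error only. Control replicate 1 lies at 71.0% and beads replicate 1 at 39.6% for stem cell-like nuclei, while the pools lie between 44.6% and 57.7%.

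No gene of DNA replication or mitosis passed in the lineage. Of 91 members of the S phase and G2 and M phase lists, 68 were tested, and 0 passed in edgeR over all 9185 genes or adjusted over the list alone. DESeq2 also called 0, and 1 member had an unadjusted p under 0.05. That gene was Dlgap5, a spindle protein gene with a log2 fold change of 1.05 ± 0.45 (SE), named after its value was seen. The members' median log2 fold change was -0.04, with 29 above 0 and 39 below. Mki67, a marker of dividing cells, was at 183, 136 and 123 CPM in control and 105, 104 and 94.7 CPM in bead libraries over the lineage. Every bead library lay below every control, with a log2 fold change of -0.46 ± 0.26 (SE, adjusted p = 1 in edgeR). In transit amplifying-like nuclei the 36 tested G2 and M phase genes had a median of -0.07 (camera adjusted p = 0.0797), and the 24 S phase genes a median of 0.01, a mean of -0.03 and an adjusted p of 0.564. With the replicate block, the G2 and M phase list passed as lower with beads there, with a median of -0.14 (adjusted p = 0.00553). No estimated correlation was run with the block, and without the block it gave an adjusted p of 0.994. The list's adjusted p over all alternatives ran from 0.000143 to 0.994, and it was 0.75 in the pools alone. Over the pools alone and with the replicate block, the number of members past the threshold was also 0.

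Within neural stem cell-like nuclei, no list of the quiescence program separated the groups. The 24 tested genes of the stem cell quiescence list had a median log2 fold change of -0.07 (camera adjusted p = 0.698), and the 8 of the activation list -0.19 (adjusted p = 0.622). The 6 Notch genes had a median of 0.10 (adjusted p = 0.416). Gfap was at 1860 CPM in controls and 1960 CPM with beads, Id3 at 260 and 160 CPM, and Egfr at 97.8 and 61.2 CPM. Their log2 fold changes were 0.07 ± 0.29, -0.34 ± 0.39 and -0.27 ± 0.44 (SE), and all 3 had the opposite sign in the pools alone. Id2 had a log2 fold change of 0.08, and Hes5, a Notch target, 0.07 ± 0.45 (SE), with the opposite sign for Hes5 in the pools alone.

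edgeR called 0 of 5066 genes in neural stem cell-like nuclei, where 76 had an unadjusted p under 0.05 and DESeq2 called 0. The smallest p values belonged to Dnm2, the endocytic GTPase dynamin 2, and Bhlhe41, a transcriptional repressor, with log2 fold changes of 1.36 ± 0.41 and 0.93 ± 0.32 (SE). Fzd3, a Wnt receptor, stood at 0.91 ± 0.32 and Cuedc2 at -0.97 ± 0.34 (SE), and all 4 had an adjusted p of 0.999. edgeR called 1 gene, Cwc22, in the pools alone. With the replicate block it called 3, which were Cwc22, Xist and Tsix. Xist and Tsix are sex-linked, and the sex of the pools is not given, so they are not read as a response.

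In transit amplifying-like nuclei, edgeR called 0 of 4649 genes, with 99 at an unadjusted p under 0.05 and 0 by DESeq2. Immediate early genes, which neurons and other cells switch on within minutes of stimulation, were higher with beads as a list. The 7 tested members had a median log2 fold change of 0.72 (camera adjusted p = 0.000471, and 0.994 with an estimated correlation), and 0 passed alone over all genes and 1, Npas4, adjusted over the list alone. Npas4 was at 0, 60.3 and 26.4 CPM in controls and 228, 167 and 123 CPM with beads, a log2 fold change of 1.88 ± 0.42 (SE, adjusted p = 0.999). Control replicate 1 held only 13 of these nuclei, and the level in beads replicate 1 rests on 11 UMI. Over all nuclei Npas4 was at 123, 94.5 and 102 CPM in controls and 84.8, 173 and 231 CPM with beads. Its higher level in the bead pools was therefore not particular to this class. Junb, Jun and Egr1 had log2 fold changes of 0.83, 0.72 and 0.56, and 2 of the 7 members lay below 0. Without beads replicate 2 the list's median was 0.40 and its adjusted p 0.14, in a range of 1.28e-07 to 0.994 over all alternatives.

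Other genes with small p values in these nuclei were Rgs2, a G protein regulator, at 1.43 ± 0.39, Actr1a at 1.34 ± 0.42 and Cdh8, a cadherin, at 1.21 ± 0.39 on the log2 scale (SE). Mki67 stood at -0.44 ± 0.32, with every bead library below every control, Hes5 at 1.16 ± 0.49 and Egfr at 0.18 ± 0.33 (SE). Top2a was at -0.23, Dcx at -0.20 and Gfap at 0.18. With a term for pilot against pool, edgeR called 5 genes, all higher with beads: Cwc22, Npas4, Rgs2, Ptgds and Meg3. It called 2 in the pools alone, Cwc22 and Ptgds, and with the replicate block 0. In the pools Rgs2 was also higher in neural stem cell-, astrocyte-, microglia- and projection neuron-like nuclei, at 0.85, 0.69, 0.74 and 1.03. Ptgds was higher there in every type tested, so neither rise was particular to this class.

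Neuroblast-like nuclei gave 0 calls of 2215 genes in edgeR and in DESeq2, with 30 at an unadjusted p under 0.05. Dcx, a marker of migrating neuroblasts, had a log2 fold change of 0.28 ± 0.35 (SE), and Gfap 0.30 ± 0.49. Csmd3 stood at -1.21 ± 0.41, Ywhah at -1.10 ± 0.39, Pwwp2a at 1.18 ± 0.42 and Tcaf1, a regulator of TRP channels, at 1.00 ± 0.37 (SE). The pools alone and the replicate block each called 1 gene, Cwc22.

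Astrocyte-like nuclei gave 0 calls of 5865 genes in edgeR and in DESeq2, with 51 at an unadjusted p under 0.05. The smallest p values were those of Ergic2 at 1.44 ± 0.47, Abhd11 at -1.31 ± 0.44, Ccdc82 at -1.15 ± 0.39, Agpat4 at 1.08 ± 0.38 and Cxxc1 at 1.18 ± 0.43 (log2 fold change ± SE). The pools alone gave 1 call in edgeR, Cwc22, and with the replicate block 0.

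The title also names the channels PKD1/2 and TRPM3 as mediators of the mechanical force. Trpm3, a calcium-permeable channel gene, was highest, among the 10 types tested, in astrocyte-like nuclei, with 375 CPM over the 6 libraries, followed by 134 CPM in neural stem cell-like nuclei. The other 8 types tested had 11.5 to 35.7 CPM, levels at which free RNA was not told apart from expression. Trpm3 had a log2 fold change of 0.51 ± 0.31 (SE) in neural stem cell-like, -0.24 ± 0.28 in astrocyte-like and 0.17 ± 0.23 in projection neuron-like nuclei, with adjusted p of 0.999, 1 and 1 in edgeR. Counts were too low for a test in the other types.

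UMI of Pkd1 and Pkd2, the polycystin genes, were counted in every type tested, at 76.5 to 179 CPM for Pkd1 and 38.8 to 106 CPM for Pkd2. Free RNA was not told apart from expression at these levels either. In neural stem cell-like nuclei Pkd1 had a log2 fold change of -0.14 ± 0.31 and Pkd2 of 0.03 ± 0.34 (SE). The values in transit amplifying-like nuclei were 0.33 ± 0.33 and 0.01 ± 0.35 (SE). Both Pkd2 values changed sign under alternatives, among them the replicate block. In the other types Pkd1 lay between -0.54 in neuroblast-like and 0.62 in endothelial-like nuclei, and Pkd2 between -0.42 in astrocyte-like and 0.40 in oligodendrocyte precursor-like nuclei. Piezo1 and Piezo2, mechanosensitive channels, were too sparse to test in any type. Piezo1 had 31 UMI in microglia-like (16.9 CPM), 31 in projection neuron-like (0.931 CPM) and 15 in endothelial-like nuclei (19.6 CPM), with 1 to 6 in the other types tested, and Piezo2 had 0 to 17 UMI per type. The list of PKD, TRP and Piezo channels had a median of 0.06 over 7 members in neural stem cell-like nuclei (camera adjusted p = 0.698).

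The beads were directed at CD24, which ependymal cells carry. Ependymal-like nuclei came almost entirely from the pools, since the pilots held 5 and 1 of them, so the test had 2 libraries per group. Genes of motile cilia were level between groups, with a median log2 fold change of -0.05 over 40 members (camera adjusted p = 0.889). Foxj1, the master regulator of motile cilia, had a log2 fold change of -0.53 ± 0.40 and Cd24a, the antibody's target, of 0.58 ± 0.35 (SE). The axonemal genes Hydin and Dnah12 stood at -0.07 ± 0.34 and 0.09 ± 0.25 (SE).

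Heat shock and unfolded protein genes were lower with beads in ependymal-like nuclei, all 11 below 0 with a median of -0.44 (camera adjusted p = 0.00152, and 0.994 with an estimated correlation). Hsph1 and Hsp90b1, chaperone genes, had log2 fold changes of -0.78 ± 0.33 and -0.73 ± 0.31 (SE), Hspd1 -0.65 and Hsp90aa1 -0.50, and 0 members passed alone. The list's adjusted p was 0.341 without control replicate 3, where its median was -0.24, and 0.0935 without beads replicate 2, in a range of 0.000198 to 0.994 over all alternatives. edgeR and DESeq2 each called 0 of 3400 genes, with 109 at an unadjusted p under 0.05 in edgeR. The nearest was Cwc22 at 2.77 ± 0.50 (SE, adjusted p = 0.09), which the replicate block called. With 2 libraries per group that block leaves hardly any freedom to estimate the spread between libraries. Left-out libraries moved the log2 fold change of Cwc22 between 1.73 and 5.04, the latter without control replicate 2. Without control replicate 2, 7 genes were called, without beads replicate 2, 4, and without beads replicate 3, 2, with Cwc22 among them each time. Without control replicate 3, 0 were called, and Cwc22 was at 1.73 (adjusted p = 0.0578). Next came Gm37494 at 1.66 ± 0.48, the Y-linked Eif2s3y at 1.81 ± 0.54, Celf4 at 1.05 ± 0.33 and Nrgn, a neuronal gene, at -0.92 ± 0.30 (SE). The sex of the pools is not given, so Eif2s3y is not read as a response.

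Endothelial-like nuclei gave the single gene past the threshold among the 10 types. Saa3, an acute phase gene of inflammation, rose from 37.5 and 42.1 CPM in the control pools to 257 and 187 CPM in the bead pools, a log2 fold change of 2.45 ± 0.39 (SE, edgeR adjusted p = 0.0156). Its counts were 7, 7, 30 and 27 UMI, a mean of 17.8, so it lies under the minimum of 20 UMI per library set beforehand. The chemokine genes Cxcl2 and Cxcl1 had log2 fold changes of 1.84 ± 0.40 and 1.19 ± 0.29 (SE, adjusted p = 0.219 and 0.401), and Ccl2 0.69 ± 0.29 (SE). The list of NF-kB and cytokine genes was higher, with a median of 0.24 over 13 members (camera adjusted p = 0.0353), and the endothelial markers lower, with a median of -0.38 over 7 (adjusted p = 0.0291). With an estimated correlation both had an adjusted p of 0.994. Slco1a4, a transporter of the blood-brain barrier, was at -0.85 ± 0.25 (SE), and Pecam1, Mecom and Abcb1a at -0.43, -0.38 and -0.39. Csf1, in the cytokine list, went the other way at -0.74.

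edgeR tested 4298 genes in these nuclei, 198 had an unadjusted p under 0.05, and DESeq2 called 0. On simulated counts of these nuclei DESeq2 recovered 57% of 4-fold changes, where edgeR recovered 79%. Saa3 was also lost with nuclei of at least 1000 UMI, where 0 genes were called. With the replicate block 9 were called: Saa3, Cwc22, Cxcl1, Cxcl2, Lcn2, Csf3, Ptgds and D10Wsu102e, higher with beads, and Slco1a4, lower. With 2 libraries per group this block leaves hardly any freedom to estimate the spread between libraries, and the pairing of the pools is assumed. Without control replicates 2 and 3 in turn, 5 and 6 genes were called, and without beads replicates 2 and 3, 5 and 11, with Saa3 among them each time. Ptgds, a prostaglandin synthase gene, had a log2 fold change of 1.13 ± 0.27 (SE, adjusted p = 0.392). In the pools it was higher with beads in the other types tested too, from 0.49 in oligodendrocyte-like to 1.36 in transit amplifying-like nuclei. Its higher level was therefore not particular to endothelial-like nuclei. The cytokine list's median was 0.59 without control replicate 3 and 0.41 without beads replicate 2. Its adjusted p was 0.215 without control replicate 2 and 0.359 without beads replicate 3, and the marker list's was 0.188 without control replicate 3 and 0.28 without beads replicate 2. Over all alternatives the adjusted p ran from 0.0121 and 0.00803, respectively, to 0.994.

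In microglia-like nuclei the genes of the resting state were lower with beads. All 15 tested members of the homeostatic list lay below 0, with a median log2 fold change of -0.61 (camera adjusted p = 1.91e-05, and 0.994 with an estimated correlation). Tmem119, a microglial surface gene, was at 101 CPM in controls and 37.5 CPM with beads. Its log2 fold change was -1.26 ± 0.38 (SE), with Siglech at -1.05, Olfml3 at -1.0 and Cx3cr1, the fractalkine receptor, at -0.69. The 7 microglia markers had a median of -0.69 (adjusted p = 0.000471, and 0.994 with an estimated correlation). Without beads replicate 2, the homeostatic median was -0.39 and that of the markers -0.42, with adjusted p of 0.0614 and 0.12. Without control replicate 1 the medians were -0.25 and -0.28, with adjusted p of 0.0445 and 0.0957, and without beads replicate 1 the marker median was -1.17. Over all alternatives the adjusted p ran from 1.85e-09 and 1.18e-07, respectively, to 0.994. Projection neuron markers in the same nuclei had a median of 0.24, 9 of 11 above 0, without passing (adjusted p = 0.188).

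No gene passed alone in microglia-like nuclei, where edgeR and DESeq2 called 0 of 6689 and 175 had an unadjusted p under 0.05 in edgeR. Cxcl2, a neutrophil chemokine gene, was at 96.6, 18.0 and 5.37 CPM in controls and 0, 215 and 160 CPM with beads, a log2 fold change of 2.88 ± 0.71 (SE, adjusted p = 0.999). In the pools alone it passed at 4.04, beside Cwc22 at 2.80, and with the replicate block 0 genes passed. Plod1 stood at -1.19 ± 0.33, Qsox1 at 1.63 ± 0.46 and Gabrg3, a neuronal receptor gene, at 0.99 ± 0.30 (SE). Cytosolic ribosomal proteins were lower, with a median of -0.19 over 50 members (camera adjusted p = 0.0207, and 0.994 with an estimated correlation), with Rpl6 at -0.51, Rpl23 at -0.48, Rps4x at -0.47 and Rpl14 at -0.32. Heat shock genes had a median of -0.30 over 14 (adjusted p = 0.00998, and 0.994 with an estimated correlation), with Hspd1 at -0.80, Atf4 at -0.63, Hspa8 at -0.48 and Hsph1 at -0.48. Without control replicates 2 and 3 the ribosomal list's adjusted p was 0.383 and 0.702, and without beads replicates 1 and 2 it was 0.901 and 0.0691. The ribosomal median was -0.08 without control replicate 3 or beads replicate 1 and -0.35 without beads replicate 3. The heat shock list's was 0.069 without control replicate 3 and 0.0707 and 0.0734 without beads replicates 2 and 3, with a median of -0.09 without beads replicate 2. Over all alternatives these ran from 2.4e-10 and 0.00115, respectively, to 0.994.

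Interferon response genes were lower with beads in 3 types, each with an adjusted p of 0.994 when the correlation was estimated. In oligodendrocyte precursor-like nuclei 14 of 15 members lay below 0, with a median log2 fold change of -0.48 (camera adjusted p = 9.62e-08, and 0.994 with an estimated correlation). Ddx58, a sensor of viral RNA, was at -0.95 ± 0.44, Oasl2 at -0.84 ± 0.38 and Isg15 at -0.84 ± 0.41 (SE). In microglia-like nuclei 22 of 24 members lay below 0 with a median of -0.36 (adjusted p = 0.000317, and 0.994 with an estimated correlation), with Stat2 at -0.64 and Ifi44 and Ifi27 at -0.67. In transit amplifying-like nuclei the median was -0.13, with 6 of 22 members above 0 (adjusted p = 0.000472, and 0.994 with an estimated correlation), with Bst2 at -1.10, Isg15 and Herc6 at -0.57 and Ifit3 at -0.42. No member passed alone. In other types the list did not pass, and its median was 0.20 in oligodendrocyte-like nuclei, with 10 of 16 above 0, and 0.14 in projection neuron-like nuclei, with 20 of 27 above 0 (adjusted p = 0.359 and 0.832). In the precursor-like nuclei all 6 astrocyte markers and 10 of 11 heat shock genes also lay below 0 without passing, with medians of -0.21 and -0.25 (adjusted p = 0.137 and 0.0581).

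The precursor-like call passed in all 6 fits that left out a library, and in the pools alone and with the replicate block. In the pools alone the list's adjusted p was 0.266 in microglia-like nuclei, with a median of -0.13, and 0.949 in transit amplifying-like nuclei, with a median of -0.02. Without control replicate 3 it was 0.0746 and without beads replicate 1 it was 0.0717 in microglia-like nuclei, with medians of -0.15 and -0.22, and the median was -0.61 without control replicate 2. For transit amplifying-like nuclei it was 0.0756 without control replicate 1 and 0.255 without beads replicate 1, with medians of -0.07 and -0.03. Their median was also -0.03 without control replicate 3, -0.36 without control replicate 2 and -0.51 without beads replicate 2. Over all alternatives the lowest adjusted p was 3.72e-08 in precursor-like and 1.56e-07 in both other types, and the highest 0.994. Differences between types were not tested.

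Oligodendrocyte precursor-like nuclei otherwise gave 0 calls of 5746 genes in edgeR and in DESeq2, with 79 at an unadjusted p under 0.05. Lancl1 stood at -1.27 ± 0.41, Rxrb at -1.36 ± 0.45, Xbp1 at -1.28 ± 0.45 and Cacybp at -1.18 ± 0.41 (log2 fold change ± SE). The pools alone and the replicate block also called 0. Oligodendrocyte-like nuclei gave 0 calls of 8371 genes in edgeR and in DESeq2, with 66 at an unadjusted p under 0.05. Arvcf was at 0.90 ± 0.27, Mindy2 at -1.02 ± 0.31, Wwp2 at 0.93 ± 0.28 and Slc2a8, a glucose transporter, at 1.17 ± 0.40 (SE). The replicate block called 3 genes there, Cwc22, Xist and Tsix, and the pools alone called 2, Cwc22 and Sav1.

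In striatal projection neuron-like nuclei, 0 of 14479 genes passed in edgeR or in DESeq2, with 84 at an unadjusted p under 0.05. Runx2 was at -0.93 ± 0.26, Bach2 at -0.73 ± 0.21 and Cyp4f13 at 1.11 ± 0.32 (log2 fold change ± SE). The reactive astrocyte list was higher, with a median of 0.33 over 26 members (camera adjusted p = 0.0158), and so was the NF-kB and cytokine list, with a median of 0.29 over 17 (adjusted p = 0.0413). With an estimated correlation both had an adjusted p of 0.994. Their members were scarce in neurons: Socs3 was at 2.13 and 4.13 CPM, Fbln5 at 1.15 and 2.37 CPM, Icam1 at 3.30 and 5.53 CPM and Tnfrsf1a at 1.35 and 2.50 CPM in control and beads. Vim was at 11.9 and 16.8, Cd109 at 1.44 and 1.91, Cxcl1 at 2.92 and 4.48 and Ccl2 at 16.7 and 23.9 CPM. Markers of other cells also lay higher there without passing. These were all 10 of astrocytes (median 0.23), all 7 of microglia (0.22), all 5 of mural cells (0.23) and 4 of 5 of endothelial cells (0.24), with adjusted p of 0.382, 0.105, 0.366 and 0.386. Mitochondrially encoded genes lay higher too, 12 of 13 above 0 with a median of 0.18 (adjusted p = 0.0581). Whether RNA of those cells carries both lists was not tested. Without control replicate 1, beads replicate 2 and beads replicate 3, the reactive astrocyte list's adjusted p was 0.641, 0.84 and 0.427, and the cytokine list's 0.877, 0.693 and 0.895. The medians there were 0.08, -0.01 and 0.14, and 0.17, 0.14 and 0.05. Without beads replicate 1 they were 0.62 and 0.47, and without control replicate 3 the reactive astrocyte median was 0.70. The reactive astrocyte list's direction turned without control replicate 1 and without beads replicate 2, and the lowest adjusted p over all alternatives was 6.15e-08 and 1.28e-07.

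In the pools alone, 9 genes passed in these neurons. Fosb, Npas4, Rgs2, Arl4d and Gadd45g were higher with beads, with log2 fold changes of 1.30, 1.15, 1.03, 1.28 and 1.64 and adjusted p from 0.0262 to 0.0359 in edgeR. Sav1, a Hippo pathway gene, fell by 1.28, and the others were Gm13889 and Gm9989, higher with beads, and Tpm3-rs7, lower. Neither fall was particular to these neurons. In the pools Sav1 was at -1.47 in oligodendrocyte-like and -1.65 in transit amplifying-like nuclei. Tpm3-rs7 was at -2.25, -1.46 and -1.28 in neural stem cell-, oligodendrocyte- and microglia-like nuclei. Over all 6 libraries Sav1 was at -0.48 in projection neuron-like nuclei. A difference between donors was not tested for these genes. The immediate early list had a median of 0.16 over 24 members in all 6 libraries and did not pass (camera adjusted p = 0.386, and 0.994 with an estimated correlation). Over the pools it passed with a median of 0.11 over 25 (adjusted p = 3.95e-07), where no estimated correlation was run. With all 6 libraries Fosb was at 16.0, 31.1 and 38.3 CPM in controls and 10.7, 93.3 and 78.6 CPM with beads, so the bead pilot lay below every control. The replicate block called 0 genes in these nuclei.

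**Figure D2:**
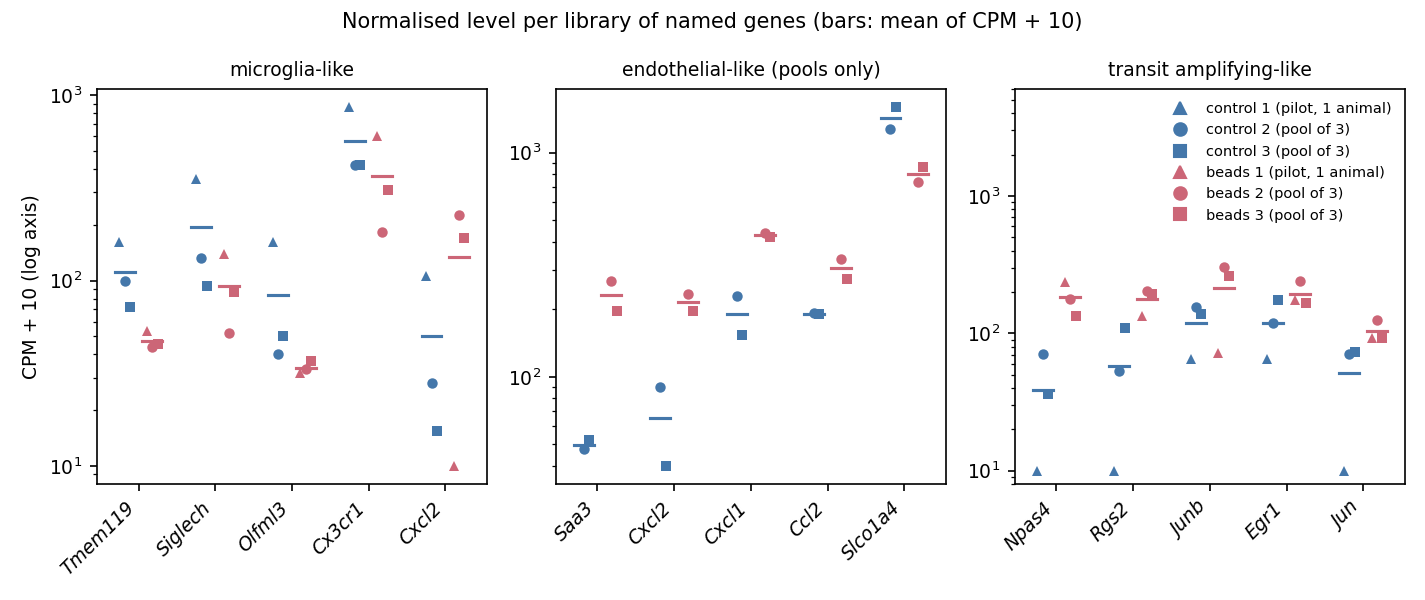
Level of named genes in each library (y axis, CPM + 10 on a log axis) in microglia-like, endothelial-like and transit amplifying-like nuclei, with bars at group means. Saa3 lies at 37.5 and 42.1 CPM in the control pools and at 257 and 187 CPM in the bead pools, before the addition of 10.

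Counting over all types, 13 of 277 combinations of list and type passed, 4 higher and 9 lower with beads. With an estimated correlation 0 passed, the smallest adjusted p being 0.994, and 0 passed by fry. Adjusted over the list alone, 2 members passed in the endothelial-like cytokine list and 1 each in the endothelial markers, the microglia markers and the immediate early genes, and 0 in the other 9. The replicate block raised the number to 41 and the pools alone gave 24. Left-out libraries moved it between 8, without beads replicate 2, and 58, without beads replicate 1. Without control replicates 1, 2 and 3 it was 31, 33 and 41.

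Cwc22, a splicing factor gene on chromosome 2 at 77881159 to 77946375 (GRCm38), recurred among the genes with small p. It was at 357, 172 and 35.1 CPM over all nuclei of control replicates 1 to 3 and at 27.1, 449 and 621 CPM in beads replicates 1 to 3. Bead pools lay above control pools in each of the 10 types, with a mean log2 ratio of 2.41 and a range of 1.88 to 2.77. The bead pilot lay below the control pilot. The log2 fold change of Cwc22 over the libraries used was 1.78 in transit amplifying-like, 2.13 in neuroblast-like and 2.09 in endothelial-like nuclei, with adjusted p of 0.999, 0.999 and 0.0797 in edgeR. Left-out libraries moved these between 0.92 and 2.28, 1.49 and 3.02, and 1.4 and 3.69, respectively.

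**Figure D3:**
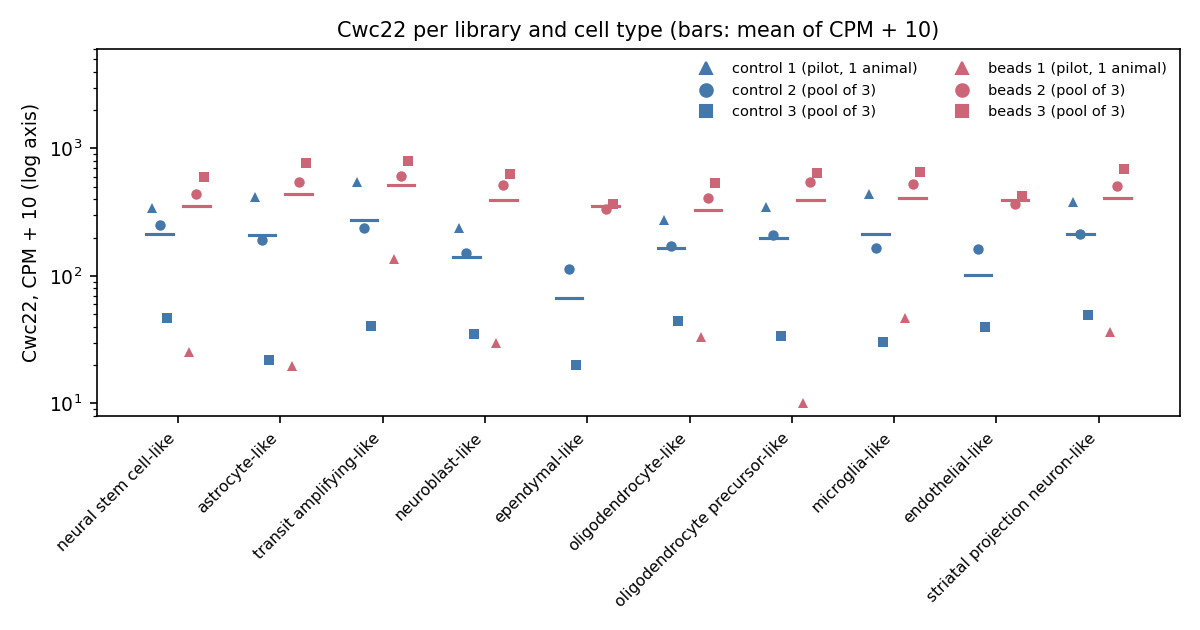
Level of Cwc22 in each type and library (y axis, CPM + 10 on a log axis), for libraries with at least 10 nuclei of the type and with bars at group means. In projection neuron-like nuclei the controls lie at 373, 203 and 39.4 CPM and the bead libraries at 26.4, 494 and 678 CPM, before the addition of 10.

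Shares of the 14 named types did not separate the groups. edgeR called 0 types, 0 had an unadjusted p under 0.05, every adjusted p was 0.992, and the exact permutation test called 0. Projection neuron-like nuclei were 53.1% ± 5.14 of named nuclei in controls and 58.9% ± 6.00 with beads, and oligodendrocyte-like nuclei 14.7% ± 5.44 and 10.5% ± 0.357 (SD, n = 3). The log2 fold change of the oligodendrocyte-like share was -0.48. It was -0.74 without control replicate 2 (edgeR adjusted p = 0.0569) and -0.21 without control replicate 1. Microglia-like nuclei were 4.15% ± 0.321 and 3.75% ± 0.0871 (SD, n = 3), every bead library below every control. Their exact permutation p was 0.1, the smallest possible, and 0.969 after adjustment over the types. The pools alone and the replicate block also called 0 types.

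**Figure D4:**
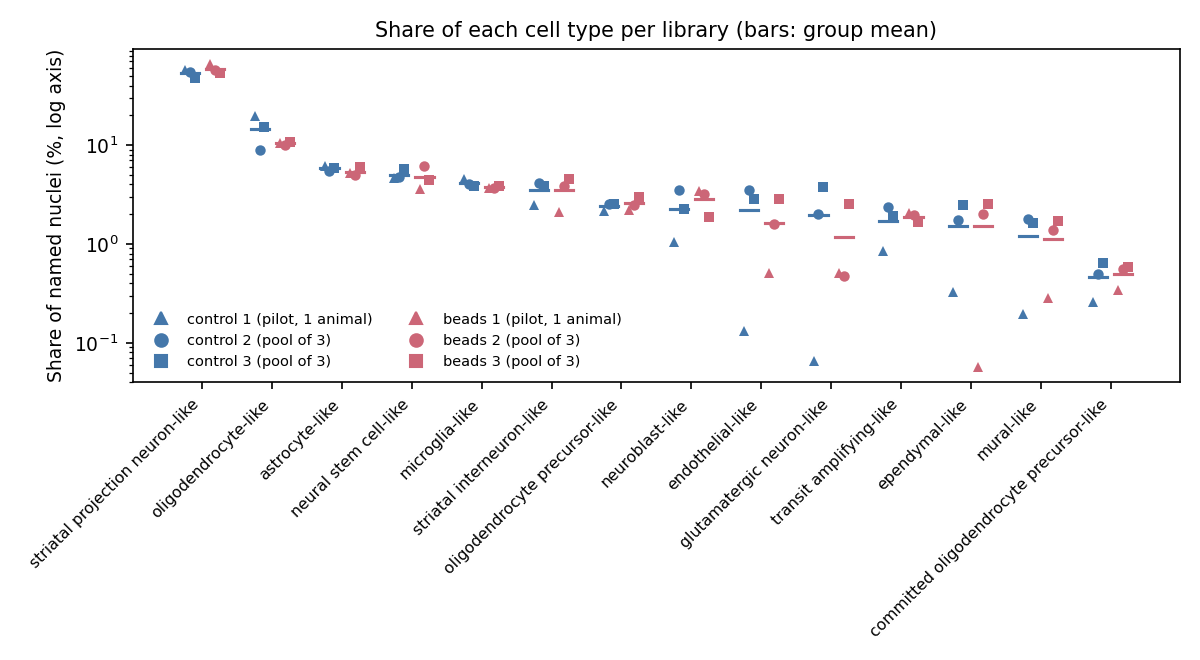
Share of each type among the named nuclei of each library (y axis, percent on a log axis), with bars at group means. Oligodendrocyte-like nuclei lie at 19.8%, 8.96% and 15.2% in controls and at 10.6%, 10.1% and 10.7% with beads.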

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

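The tests of the Cwc22 pattern and the counts over other splits were set up after the result was seen. The other tests had a bound set beforehand, but the requirement that a value pass it by more than its spread was applied after the values were seen. Without that requirement, both values would have been read as arguing against RNA from other cells. That reading would not hold. The immediate early ratio used bead libraries only, and the microglia median pools markers that went both ways.

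Several unnamed clusters, which no comparison above uses, held a larger share of 1 bead library or of both bead pools than of any control. Only shares higher in bead libraries were looked for, not lower ones. The biggest unnamed cluster, described above, held a smaller share of both bead pools than of either control pool. The cluster led by Cpne7, Cpne4 and Tshz2, nearest to septal neurons, made up 9.35% of beads replicate 3 (95% interval 8.75% to 9.98%), against 0.58%, 4.07% and 1.71% in the controls and 0.61% and 1.38% in beads replicates 1 and 2. A cluster with oligodendrocyte and microglia genes and a median of 5148 UMI made up 4.15% of beads replicate 2 and 4.27% of beads replicate 3, against at most 2.39% in a control. Another with oligodendrocyte genes and a median of 3644 UMI made up 2.46% and 2.73% of the same libraries, against at most 1.72%. The named oligodendrocyte-like clusters had medians of 1069 and 1083 UMI, and of the bead pilot, 0.11% and 0.0% lay in these unnamed clusters. A cluster led by Ttr, Mgp and Hbb-bs made up 3.73% of beads replicate 2, 0.0% of the other bead libraries and at most 0.04% of any control. A lineage sub-cluster led by S100a6, Vim and Lcn2 made up 2.18% of beads replicate 3, against at most 0.98% in a control and 0.17% and 0.88% in beads replicates 1 and 2. No explanation of these shares was tested.

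Cwc22 was higher in the bead pools than in the control pools and lower in the bead pilot than in the control pilot. In the pilots the median log2 ratio of beads over control was -3.6 (SD 1.01 over 8 types), but with 1 animal against 1 the treatment and a difference between animals cannot be told apart. The ratio between pools varied little over the 10 types (SD 0.3), and control libraries differed among themselves by up to 10.2-fold. A donor variant, such as the copy number difference known at this locus between mice, is therefore a candidate explanation, found and tested on the same data. Which animals carry it was not tested.

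Immediate early genes were higher with beads in transit amplifying-like nuclei, and RNA from the abundant projection neurons might account for it. In bead libraries the members' level relative to projection neuron-like nuclei had a median ratio of 0.859 (SD 0.6 over 7), while 11 projection neuron markers had ratios of 0.4 to 0.814. The median lay above the highest marker, the bound set beforehand, by less than its spread. Junb, at 0.637, Npas4, at 0.55, and Homer1, at 0.45, lay within the markers' range, and Jun, at 2.23, Jund, at 1.02, Egr1, at 0.936, and Egr3, at 0.859, above it. Free RNA and a response of these cells to beads or to handling cannot be told apart here, because the members go both ways. The ratio also holds no comparison with control libraries, so it does not address the difference between groups.

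Homeostatic genes were lower with beads in microglia-like nuclei, and more RNA of other cells in those nuclei could dilute them. The markers of other types had a median log2 fold change of -0.03 there (SD 0.32), with 22 of 48 above 0, while 9 of the 11 projection neuron markers lay above 0 (median 0.24, adjusted p = 0.188). The median over all markers met the bound set beforehand, but by less than its spread. The dilution and a change of the microglia cannot be told apart, because the markers go both ways. The list of activated microglia genes had a median of -0.23 over 20 members.

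With 6 libraries in groups of 3 there are 10 splits, too few to give a share under 0.05. The real split called 0 genes in each of the 8 types with 6 libraries, and the highest other split called 2 in each. In every type that split set control replicate 1 and beads replicates 1 and 3 against the rest. These had the least Xist, at 8.25, 3.64 and 136 CPM over all nuclei. Control replicates 2 and 3 and beads replicate 2 had 1080, 1360 and 1390 CPM. That split therefore also parts the libraries by a sex-linked gene. For proliferation genes the real and highest other counts were both 0, and for types with a changed share 0 and 1. For gene lists in those types the real split gave 10 and the highest other 92. Of the 10 splits, 8 gave as many lists as the real split or more, the real split included, so the number of list calls does not set it apart. The splits that keep both pilots on the same side gave 74 or more, several times the real count, which points to a structure of pilots against pools. Among the splits that part every pair, the real split gave 10 and the others 23, 11 and 6, and these others mix treated and untreated libraries. In the pools alone the lists passing numbered 24 over all types.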

How the results depend on the processing

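The mitochondrial limit of 5% and the other clustering seed were chosen after seeing the data. Of 220 alternatives to the 15 tested results, 166 were labelled the same. Of the others, 47 moved past the threshold or gave more calls, 4 fell short of it or gave fewer and 3 reversed. Most of these results are numbers of calls. For them the label compares the number only, not the direction or which genes or lists were called. A number close to the main number was also labelled the same. A result without calls could not give fewer, so for such results the label could show only the same or more. Of 1998 alternatives to 135 named gene values, 1913 kept direction and side of the threshold. The rest comprised 38 that moved past the threshold, 2 that fell short and 45 that reversed. Unless a cause is stated, it was not tested. Ependymal-like and endothelial-like nuclei were tested in the pools from the start, so neither the pilot term nor the pools alone gave them another value. Fits that leave such a group with 1 library assume that it varies like the other group.

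Without a filter on low counts, edgeR called 1 gene in neural stem cell-, astrocyte-, transit amplifying- and oligodendrocyte-like nuclei, 2 in neuroblast-, ependymal-, oligodendrocyte precursor- and microglia-like nuclei and 3 in endothelial-like nuclei. Ttr, abundant in beads replicate 2, was called in each of them. The replicate block called 3 genes in neural stem cell-like, 1 in neuroblast-like, 1 in ependymal-like, 3 in oligodendrocyte-like and 9 in endothelial-like nuclei. It raised the gene lists passing to 41 and changed no other call, leaving the differences at 1.91 for the cycling share of the neurogenic lineage and -7.86 for the stem cell share of the neurogenic lineage. The term for pilot against pool called 5 genes in transit amplifying-like and 1 in neuroblast-like nuclei.

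The pools alone called 1 gene in neural stem cell-like, 1 in astrocyte-like, 2 in transit amplifying-like, 1 in neuroblast-like, 2 in oligodendrocyte-like, 2 in microglia-like and 9 in projection neuron-like nuclei, and 24 gene lists. They turned the differences to -1.95 percentage points for the cycling share of the neurogenic lineage and 3.89 for the stem cell share of the neurogenic lineage. DESeq2 called 0 genes in endothelial-like nuclei, as did nuclei with at least 1000 UMI, and its size factors in edgeR called 1 in ependymal-like nuclei. Keeping doublets called 3 in ependymal-like and 3 in endothelial-like nuclei, and the 5% limit called 1 and 5. The other seed called 1 gene in astrocyte-like nuclei, Cwc22, where control replicate 1 kept 11 of its 94 nuclei. An estimated correlation left 0 gene lists.

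With each library left out in turn, the genes called ranged from 0 to 2 in neural stem cell-, transit amplifying- and oligodendrocyte precursor-like nuclei, 0 to 1 in neuroblast-like, 0 to 7 in ependymal-like and 5 to 11 in endothelial-like nuclei, and stayed at 0 in the other types. Without beads replicate 2, Xist and Tsix were called in neural stem cell-, transit amplifying-, oligodendrocyte precursor-, ependymal- and endothelial-like nuclei. Gene lists ranged from 8 to 58, the cycling difference from -0.726 to 3.92 and the stem cell difference from -14.5 to -1.25. Proliferation genes and types with a changed share stayed at 0.

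No named gene whose sign reversed had passed the threshold. In neural stem cell-like nuclei, Pkd2 was -0.02 with the replicate block and, in the pools alone, Pkd2 was -0.10, Egfr 0.02, Gfap -0.03, Id3 0.13 and Hes5 -0.06. Hes5 was -0.11 with doublets kept, -0.14 at the 5% limit and -0.10 with the other seed. In transit amplifying-like nuclei, Pkd2 was -0.15 in DESeq2, -0.01 with its size factors, -0.03 without the filter, -0.01 with the block, 0.00 with the pilot term, -0.11 at 1000 UMI and -0.17 at the 5% limit. Egfr was -0.02 there at 1000 UMI. With doublets kept, Gfap was -0.02 in neuroblast-like and Hydin 0.00 in ependymal-like nuclei.

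Left-out libraries moved log2 fold changes across 0 in these ranges. In neural stem cell-like nuclei they were -0.07 to 0.30 for Pkd2, -0.69 to 0.10 for Egfr, -0.03 to 0.20 for Id2, -0.89 to 0.10 for Id3 and -0.06 to 0.22 for Hes5. In transit amplifying-like nuclei they were -0.27 to 0.10 for Pkd2, -0.02 to 0.44 for Egfr, -0.40 to 0.03 for Top2a and -0.43 to 0.42 for Gfap. In ependymal-like nuclei they were -1.03 to 0.14 for Pkd1, -0.79 to 0.01 for Foxj1, -0.40 to 0.33 for Hydin and -0.07 to 0.31 for Dnah12. Elsewhere they were -0.17 to 0.15 for Pkd1 in astrocyte-like, -0.26 to 0.66 for Gfap in neuroblast-like, -0.05 to 0.31 for Pkd1 and -0.03 to 0.52 for Pkd2 in oligodendrocyte precursor-like, -0.68 to 0.01 for Pkd2 in endothelial-like and -0.02 to 0.39 for Trpm3 in projection neuron-like nuclei.

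Depth limits the rarer types: libraries summed to 13181 to 178500 UMI in neuroblast-like and 18535 to 280771 in transit amplifying-like nuclei. Genes without overlap between groups were 4.3% to 9.3% of those tested in the 3 against 3 comparisons, where chance gives 10%.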

Other observations

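Ttr, the transthyretin gene of the choroid plexus, had 26564 UMI in beads replicate 2 and at most 109 in any other library. It reached 258 CPM in neural stem cell-like and 222 CPM in astrocyte-like nuclei of that library, against 3.32 and 7.75 CPM in control replicate 2. Xist, expressed from the inactive X chromosome, had 28, 18168 and 23999 UMI in control replicates 1 to 3 and 14, 26032 and 2372 UMI in beads replicates 1 to 3. The Y-linked Uty was at 118, 57.9 and 36.7 CPM in the controls and 91.8, 41.2 and 100 CPM in the bead libraries. Low Xist went with high Uty in control replicate 1 and beads replicates 1 and 3, so sex composition differed between libraries of the same group. The calls of Xist and Tsix above are not read as a response to beads.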
